A study of Mus musculus with 8 samples.

How the data were processed

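Total RNA was extracted with TRIzol from the hearts of 8 female mice, labelled with biotin and hybridised to Affymetrix mouse arrays, 1 per heart, by the maker's standard protocol. The deposited values were probe set intensities that the authors made with GCOS 1.3 and RMA, per the submitters' processing notes, which give neither the order nor the RMA version. RMA corrects the background, makes the arrays' distributions equal and summarises each probe set across arrays. The intensities were on the linear scale, with array medians of 34.3 to 37.3 and maxima of 19306 to 20716, and log2 was taken here. No filter was applied to dim probe sets, and no pseudocount was needed, the lowest array minimum being 4.90. No arrays were identical, and every column was assigned to a sample.

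Samples were grouped by the labels into WT and KO at 4 and 10 weeks, 2 mice each. The sources used here give no batch or processing day, and the 4 mice of an age were littermates, so litter was the same for KO and WT of an age and differed between ages. The labels do not say whether the replicate numbers pair KO with WT mice, and they were not treated as pairs.

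The table held 45101 probe sets. 64 Affymetrix control probe sets were left out, so 45037 were left, of which 34945 name 1 gene in the platform annotation, 932 name several and 9160 name none. For each of the 18193 genes the probe set with the highest mean over the arrays was used, and 9010 genes had more than 1. Symbols were matched to a RefSeq gene table by Entrez ID for 34741 probe sets. Positions on the genome are not given, because the probe sets were matched to genes by name. 1 planned result, on a single gene, is not reported here. Of the probe sets of 161 named genes at 10 weeks, 89 genes had a further probe set, 10 of these had at least 1 of opposite sign, and none of those passed the test. For 33 of the 89 every further probe set gave under 60% of the difference of the probe set used, a bound chosen after the values were seen.

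A linear model with 1 mean per group was fitted to all 8 arrays in limma 3.58.1 (R 4.3.3), with moderated variances (eBayes, no trend, not robust), 4 residual degrees of freedom and 9.33 in total after moderation. The median SE of a KO minus WT difference was 0.145 on the log2 scale. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes were called higher or lower. The comparisons were KO minus WT at each age, the difference of these differences, and 10 minus 4 weeks within each genotype. Agreement between the ages was given as Pearson and Spearman correlations across genes. Groups of 2 allow neither a test of an outlying sample within a group nor a count over other divisions of the samples into groups.

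42 gene lists of 741 entries, 683 of them measured, were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes. The p-values were adjusted over the 42 lists within a comparison, and members were also adjusted over the list alone. 56 different listed genes were not measured. The lists cover ATF4 and integrated stress response targets, serine, one-carbon and proline synthesis, cytosolic tRNA synthetases, chaperones of the endoplasmic reticulum and of mitochondria, iron handling, heme synthesis, iron-sulfur cluster assembly and proteins, complexes I to IV, ATP synthase, mitochondrial ribosomal proteins, the tricarboxylic acid cycle, fatty acids, glycolysis, mitochondrial biogenesis, hypertrophy, contraction, extracellular matrix, NRF2 targets, antioxidant enzymes, p53 targets, autophagy, cell cycle, hypoxia, cholesterol, metallothioneins, interferon, immediate early genes, the circadian clock, and markers of 10 cell types or tissues. Several share members, such as Sdhb and Hmox1. The lists, the tests, the rule for naming genes and the alternatives were chosen before the data were examined, except where a test or alternative is said to be chosen later.

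Genes were named by rule: the 10 largest rises and falls per age among called genes whose KO arrays all lay beyond the WT arrays, leaving out clone-like symbols. Up to 4 called members per list with the largest difference were added, or the 2 with the smallest p where none was called. The 5 largest rises and falls were taken for the difference between ages and for each age comparison. Genes given as levels on single arrays (Alb, Myl7, Kap) were picked after their values were seen.

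The alternatives were all probe sets tested singly, the mean of a gene's probe sets, probe sets of shared sequence left out, filters on genes below the median level or below a mean log2 of 6, quantile normalization again, arrays centred on their medians, eBayes with trend and robust settings, array weights, only the groups of a comparison, the replicate number as a block, and each array left out in turn. Where an array left out leaves a group with 1, that heart is assumed to vary like the other groups. Liver and atrial scores as covariates were added after seeing the data. Random lists (10000) and bootstrap intervals (95%, resampling the genes of a list) were drawn with a fixed seed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

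The steps were tested on simulated data of the 10-week comparison with 18193 genes. Of 100 genes changed 2-fold 75 were found and of 100 changed 4-fold 99, 0 with the wrong sign, with 4 calls among unchanged genes. A shifted list was found by camera, and 0 of 40 unshifted lists were called. The simulated genes varied independently, with the same spread in every group. The simulation therefore does not test camera's preset correlation on genes that vary together.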

Results

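Messenger RNA levels were measured in the hearts of female mice with a conditional gene deletion under the MCK (muscle creatine kinase) driver, and in wild-type littermates. Knock-out (KO) and wild-type (WT) mice were taken at 4 and at 10 weeks of age, 2 mice per genotype and age, with 1 Affymetrix mouse array per heart and 8 arrays in all. The median intensity of an array lay between 34.3 and 37.3 on the linear scale, and the number of arrays, 2 per group, limits the precision. The 4 mice of an age were littermates, so in a comparison of the ages, age, litter and any processing day cannot be told apart.

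The hearts of 10-week KO mice stood apart from the others across all genes. The first principal component carried 51.9% of the variance and put these 2 hearts at 46.7 and 39.1, with the other 6 between -24 and -6.1. The second carried 24.3% and put replicate 1 of the 10-week WT hearts at -43.3, with the others between -4.2 and 13.9. Kap, a kidney gene, read log2 9.73 on that array and 7.29 on replicate 2 of its group. Alb, the liver's serum albumin, ranged from log2 5.19 to 11.05 over the 8 arrays and read 10.94 and 7.78 on the 10-week WT pair against 5.19 and 6.76 on the KO pair, a difference that did not pass the test (adjusted p = 0.183). The atrial genes Sln, a regulator of the sarcoplasmic calcium pump, and Myl7, the atrial myosin light chain, differed within groups as well. In the 4-week KO pair Sln read 10.14 and 11.8 and Myl7 11.54 and 12.97.

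**Figure D1:**
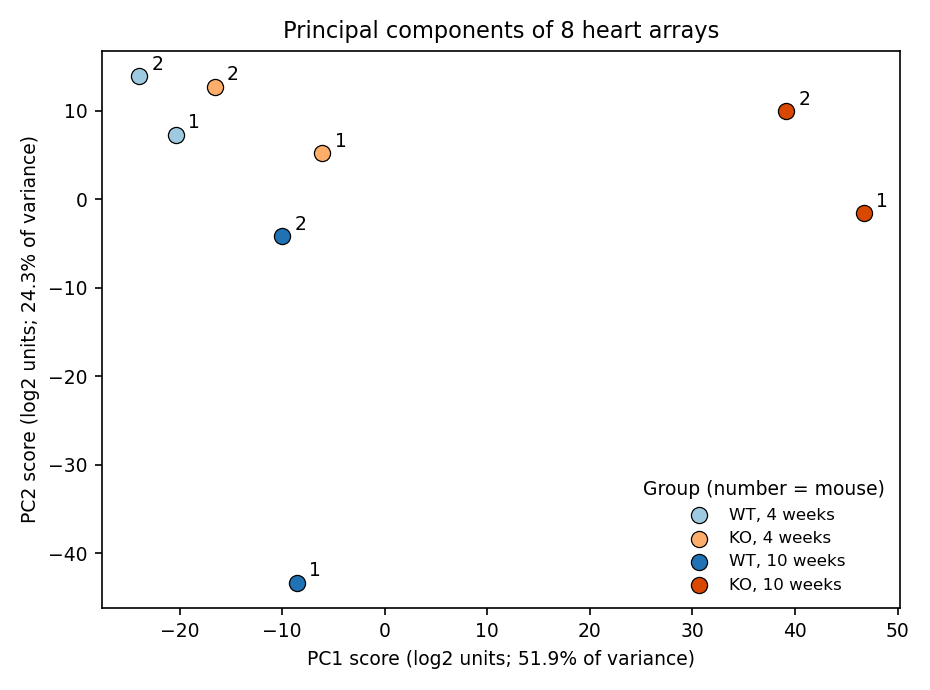
Principal components of the 8 arrays over all genes (axes: component scores from log2 intensities), 1 point per heart and 1 colour per group. The 10-week KO hearts lie at 46.7 and 39.1 on the first component, and replicate 1 of the 10-week WT hearts lies at -43.3 on the second.

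The comparison of KO with WT at 4 weeks asks which genes differed at the younger age, and 5 genes rose in KO. Nmrk2, a nicotinamide riboside kinase that makes a precursor of NAD, rose from log2 6.94 ± 0.19 to 10.53 ± 0.69 (SD, n = 2 per group), a difference of 3.59 ± 0.33 (SE) or 12-fold. Asns, asparagine synthetase and a target of the stress-response factor ATF4, rose by 2.95 ± 0.17 on the log2 scale. Cpxm2, a secreted protein of the carboxypeptidase family, rose by 2.42 ± 0.24 on the brighter of its probe sets and read 0.30 (adjusted p = 1) on the other, and Nppb, the natriuretic peptide of a loaded heart, by 1.97 ± 0.19. Bdh1, which oxidises a ketone body, rose by 1.56 ± 0.16. In limma with Benjamini-Hochberg adjustment over 18193 genes, the adjusted p was 0.000414 for Asns and 0.0103 for each of the other 4, with both KO arrays above both WT arrays. 0 genes fell, and 679 genes had an unadjusted p under 0.05. Some settings also called genes lower: 4 of 14 with array weights, 3 of 12 without either 10-week WT array, 1 of 5 without 4-week WT replicate 1, 1 of 3 without 4-week KO replicate 2, and 2 of 4 with liver and atrial scores as covariates. Lgals3, the lectin of activated macrophages, differed by 2.03 ± 0.26 and did not pass (adjusted p = 0.0579).

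With 1 array fewer, 4 of these genes could miss the threshold while their differences stayed of like size. Nmrk2 no longer passed without 4-week WT replicate 1 (3.45, adjusted p = 0.134), WT replicate 2 (3.72, 0.137) or KO replicate 1 (3.10, 0.0585). Cpxm2 no longer passed without 4-week KO replicate 1 (2.41, 0.149) or 2 (2.42, 0.186), nor Nppb without KO replicate 1 (1.89, 0.149) or 2 (2.05, 0.112). Bdh1 no longer passed without WT replicate 1 (1.69, 0.0699), WT replicate 2 (1.42, 0.281) or KO replicate 2 (1.37, 0.127). The count was 3 without 4-week WT replicate 2, KO replicate 1 or KO replicate 2, and 12 without either 10-week WT array. Asns kept its call in each of these settings.

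At 4 weeks few members of the gene lists passed over all genes. Of 27 measured ATF4 and integrated stress response targets, Asns passed over all genes and 11 passed adjusted over the list alone, with a median log2 difference of 0.30. The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, had a median of 0.30 and 4 of 19 members higher adjusted over the list alone. Gars differed by 0.70 ± 0.14 and Sars by 0.60 ± 0.12, and neither passed over all genes (adjusted p = 0.541 for each). In serine, one-carbon and proline synthesis 4 of 16 members were higher adjusted over the list alone, with Mthfd2 at 1.49 ± 0.21 (adjusted p = 0.128) and Psat1 at 1.26 ± 0.27 (0.541). Of 16 hypertrophy genes Nppb passed over all genes and 5 adjusted over the list alone, with a median of 0.35. Of the 9 atrial markers 7 were higher adjusted over the list alone, with a median of 1.27, Nppa at 1.28 ± 0.24 (adjusted p = 0.487) and Sln at 1.80 ± 0.48 (0.882). The hypoxia list had a median of -0.24 and 2 of 15 members lower adjusted over the list alone, Egln3, an oxygen-sensing hydroxylase, being at -1.18 ± 0.19 (adjusted p = 0.198).

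Camera called 16 of the 42 lists at 4 weeks, 9 up and 7 down. The adjusted p was 3.19e-12 for the ATF4 list, 1.9e-08 for the synthetases, 1.96e-08 for extracellular matrix, 3.38e-08 for atrial markers, 1.79e-07 for serine, one-carbon and proline synthesis, 4.5e-07 for hypoxia and 1.78e-06 for hypertrophy. With an estimated correlation none of the 42 was called, the lowest adjusted p being 0.336, shared by these lists except the synthetases at 0.442. Fry called 0 of the 42, with a lowest adjusted p of 0.294 and a lowest unadjusted p of 0.0132. Further camera calls went up for cell cycle (adjusted p = 4.56e-05), mesothelial markers (0.000138) and immediate early genes (0.00292), each with adjusted p = 0.336 with an estimated correlation. Calls down were for cardiomyocyte contraction (0.000261), complex I (0.00448), the circadian clock (0.00448), the tricarboxylic acid cycle (0.0208), iron-sulfur proteins (0.0214) and glycolysis (0.0329). With an estimated correlation these had an adjusted p of 0.622, 0.592, 0.336, 0.754, 0.411 and 0.754. Camera no longer called complex I (adjusted p = 0.0647) or the clock (0.164) without 4-week KO replicate 1, nor immediate early genes (0.0686) or mesothelial markers (0.0656) without KO replicate 2. It no longer called the acid cycle without WT replicate 2 (0.146) or KO replicate 2 (0.336), iron-sulfur proteins without WT replicate 2 (0.0808) or KO replicate 1 (0.262), or glycolysis without any of the 4 arrays of that age (0.0737 to 0.136). The lists on iron, heme, iron-sulfur clusters and the stress response were drawn up with knowledge of published work on this mouse model, so they are not independent evidence.

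**Figure D2:**
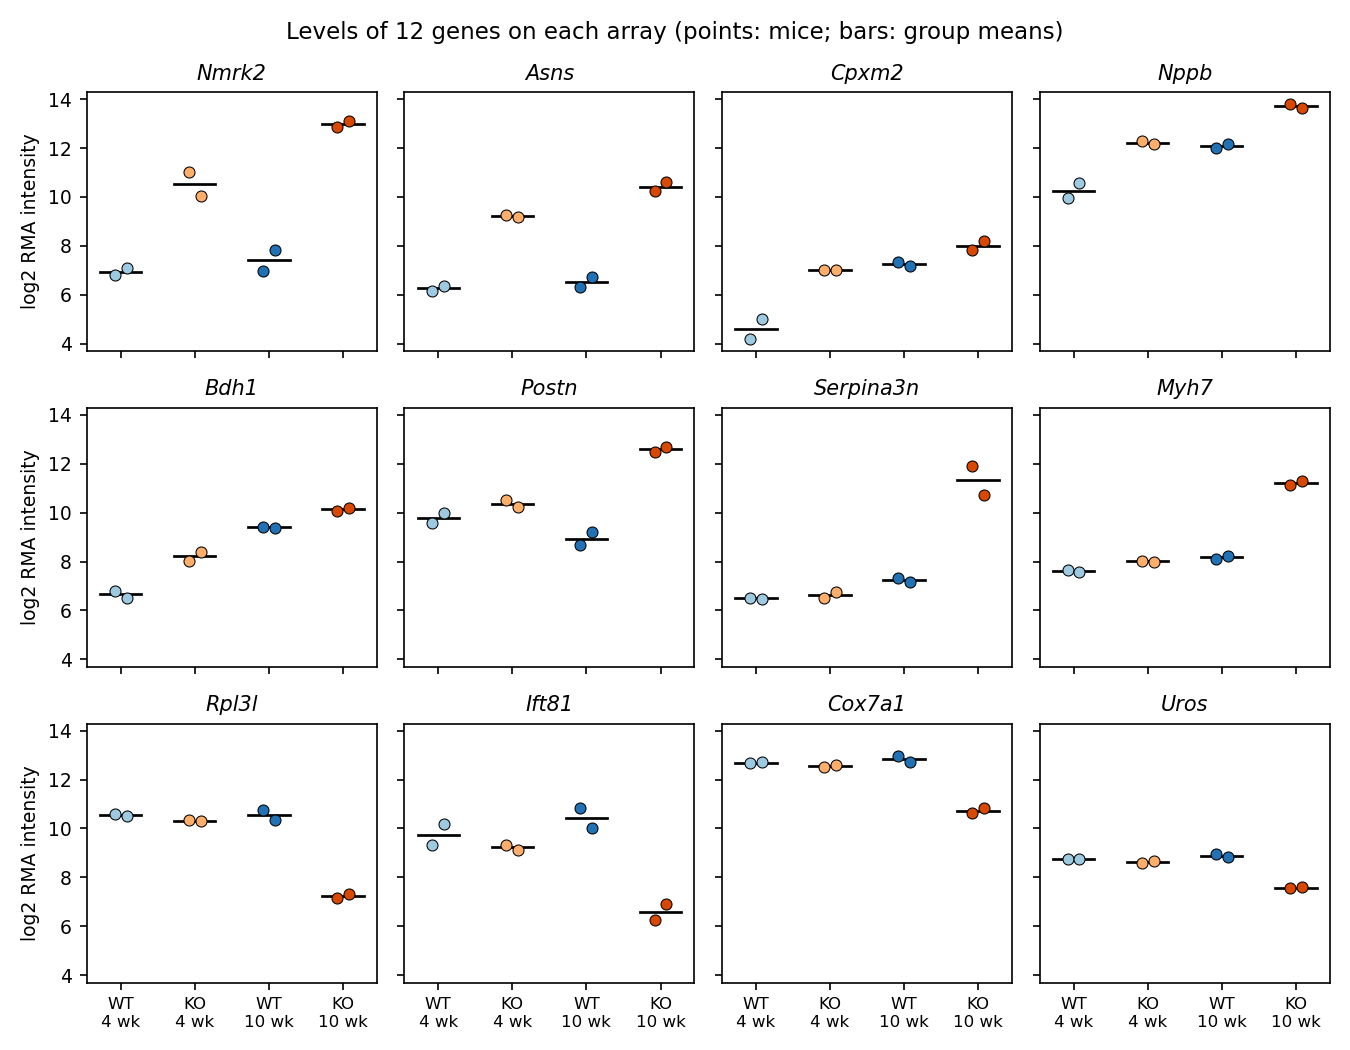
Log2 RMA intensity (vertical axis) of 12 genes on each of the 8 arrays, by group on the horizontal axis, with a point per heart and a bar at each group mean. Nmrk2 averages 6.94 in 4-week WT, 10.53 in 4-week KO, 7.40 in 10-week WT and 12.98 in 10-week KO hearts.

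The comparison at 10 weeks asks which genes differed in the older hearts. Nmrk2 rose by 5.57 ± 0.33 on the log2 scale (SE, n = 2 per group), 47.6-fold, and Asns by 3.91 ± 0.17. Serpina3n, an acute-phase protease inhibitor, rose by 4.06 ± 0.30, and the matrix genes Timp1, Postn, Col8a1 and Cilp rose by 3.74 ± 0.33, 3.67 ± 0.20, 3.59 ± 0.26 and 3.58 ± 0.20. Psat1, of serine synthesis, rose by 3.45 ± 0.27, Lgals3 by 3.30 ± 0.26 and Aldh18a1, of proline synthesis, by 3.15 ± 0.34. Ift81, of ciliary transport, fell by 3.85 ± 0.34, the heart receptor gene Gpr22 fell by 3.33 ± 0.24 and Rpl3l, the ribosomal protein of striated muscle, fell by 3.31 ± 0.15. Lrtm1, a membrane protein with leucine-rich repeats, fell by 3.14 ± 0.20, Cmss1, a ribosome-biogenesis gene, fell by 3.09 ± 0.20, and Ces1d, a lipid hydrolase, fell by 3.08 ± 0.16. Gstk1, the mitochondrial and peroxisomal glutathione transferase, fell by 2.93 ± 0.18, the channel gene Pkd2l2 fell by 2.83 ± 0.16 and Asb5, of a ubiquitin ligase family in muscle, fell by 2.70 ± 0.16.

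Over 18193 genes, 945 were higher and 1254 lower in 10-week KO (limma, Benjamini-Hochberg), 2199 in all, of which 771 differed at least 2-fold. The adjusted p of the genes just named lay between 1.27e-05, for Asns and Rpl3l, and 0.000616, for Aldh18a1, and each kept its call without any single array. Other probe sets of some of them gave less: the 4 others of Aldh18a1 gave 1.10 to 1.48, those of Cmss1 -0.10 and -0.01, and that of Pkd2l2 -0.01. Kap fell by 2.70 ± 0.63 (adjusted p = 0.0218) and lost its call without 10-week KO replicate 1 (0.112) or 2 (0.103), with trend and robust settings (0.166) and with only the 10-week groups (0.0853). The count was 1154 without 10-week KO replicate 1, 1324 without KO replicate 2, 1998 without WT replicate 1, 1585 of them in common with all arrays, and 3244 without WT replicate 2. The balance of directions moved too, with 718 higher and 1280 lower without WT replicate 1 but 1674 higher and 1570 lower without WT replicate 2.

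Genes of the amino acid stress response rose at 10 weeks. Of 27 ATF4 targets 16 were higher and 1 lower over all genes, and 19 and 1 adjusted over the list alone, with a median of 0.93. Ddit3, a transcription factor of the stress response, rose by 2.59 ± 0.27, Chac1, which degrades glutathione, by 2.49 ± 0.23 and Trib3, a pseudokinase induced by ATF4, by 2.03 ± 0.22. Of 19 tRNA synthetases 13 were higher and 1 lower (15 and 1 adjusted over the list alone), with a median of 0.95, led by Gars at 1.87 ± 0.14, Eprs at 1.69 ± 0.26, Tars at 1.43 ± 0.23 and Nars at 1.38 ± 0.18. In serine, one-carbon and proline synthesis 9 of 16 were higher and 1 lower, the same numbers adjusted over the list alone, with a median of 0.56. The mitochondrial folate enzymes Mthfd2 and Aldh1l2 rose by 2.46 ± 0.21 and 1.38 ± 0.22. Camera gave an adjusted p of 4.58e-14, 1.48e-10 and 0.000149 for these 3 lists, and adjusted p = 0.217, 0.258 and 0.217 with an estimated correlation.

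Respiratory chain subunits fell at 10 weeks. Of 33 complex I subunits 26 were lower over all genes and 30 adjusted over the list alone, with a median of -0.79. Ndufb2 fell by 1.51 ± 0.22, Ndufa7 by 1.32 ± 0.19, Ndufa8 by 1.23 ± 0.13 and Ndufs4 by 1.21 ± 0.14. Of 14 subunits of complexes II and III 7 were lower (9 adjusted over the list alone), median -0.57, with Uqcr11 at -1.53 ± 0.17, Uqcrq at -1.21 ± 0.17 and Uqcrh at -0.93 ± 0.16. The value of Uqcrq was that of its brightest probe set: the 3 others gave -0.04, -0.22 and 0.14, and its call was lost with the mean of its probe sets (-0.33, adjusted p = 0.0875) and with probe sets of shared sequence left out (-0.22, 0.414). Of 12 complex IV subunits 6 were lower (6, and 1 higher, adjusted over the list alone), median -0.37, with the muscle isoforms Cox7a1 at -2.13 ± 0.13 and Cox8b at -1.14 ± 0.15. Of 17 ATP synthase subunits 9 were lower (12, and 1 higher, adjusted over the list alone), median -0.54, with Atp5e at -1.72 ± 0.24. Of 76 mitochondrial ribosomal proteins, which make the subunits encoded in mitochondrial DNA, 43 were lower and 1 higher (57 and 2 adjusted over the list alone), median -0.63. Mrps21 fell by 1.49 ± 0.18 and Mrpl36 by 1.45 ± 0.22. Camera gave an adjusted p of 3.26e-21 for complex I, 2.3e-06 for complexes II and III, 0.000161 for complex IV, 2.3e-06 for ATP synthase and 5.25e-21 for the ribosomal proteins. With an estimated correlation these were 0.11, 0.148, 0.217, 0.11 and 0.217. Without 10-week KO replicate 1 the lower members were 4 for complexes II and III, 5 for ATP synthase and 20 for the ribosomal proteins. Without KO replicate 2 they were 3 for complex IV, 5 for ATP synthase and 27 for the ribosomal proteins, and without WT replicate 1 complex IV had 3. The 3' minus 5' signal of the Gapdh control probe sets was higher in 10-week KO than in WT by 0.07 on the log2 scale.

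Some fatty acid and hypoxia genes fell as well. Of 25 genes of fatty acid uptake and oxidation 12 were lower (16, and 1 higher, adjusted over the list alone), median -0.52. Etfb, which passes electrons from fatty acid oxidation, fell by 1.67 ± 0.14 and Cpt2, of acylcarnitine import, by 1.48 ± 0.17. Eci1 and Decr1, of unsaturated fatty acid oxidation, fell by 1.11 ± 0.16 and 1.10 ± 0.14. Of 22 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase 3 were lower (9 adjusted over the list alone), median -0.20, with fumarase, Fh1, at -1.31 ± 0.15. Of 17 regulators of mitochondrial biogenesis 3 were lower, the same adjusted over the list alone, median -0.29, with the mitochondrial RNA methylase Tfb1m at -1.28 ± 0.17. Of 15 hypoxia genes 7 were lower (9, and 2 higher, adjusted over the list alone), median -0.56, with Egln3 at -1.67 ± 0.19, the mitochondrial protein Higd1a at -1.54 ± 0.20 and the mitophagy receptor Bnip3 at -1.28 ± 0.22. Camera gave an adjusted p of 2.76e-09, 0.000996, 0.0123 and 0.00306 for these 4 lists, and adjusted p = 0.288, 0.465, 0.324 and 0.217 with an estimated correlation. Without 10-week KO replicate 1 the lower members were 7 for fatty acids and 1 for biogenesis. Without KO replicate 2 they were 6 for the acid cycle, 1 for biogenesis and 4 for hypoxia, and without WT replicate 1 biogenesis had 5. The median of the acid cycle was -0.35 and -0.13 without WT replicate 1 and 2 and -0.09 and -0.40 without KO replicate 1 and 2, and that of biogenesis -0.12 without WT replicate 2. Camera no longer called the acid cycle or biogenesis without WT replicate 2 (adjusted p = 0.131 and 0.251) or KO replicate 1 (0.13 and 0.0785).

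Some heme synthesis genes fell, and iron genes went both ways. Of 12 heme synthesis genes 5 were lower, the same adjusted over the list alone, median -0.55. Uros, Urod and Alad, enzymes of the porphyrin pathway, fell by 1.32 ± 0.11, 1.08 ± 0.16 and 1.07 ± 0.19, and the porphyrin transporter Abcb6 by 0.87 ± 0.12. Of 23 genes of iron-sulfur cluster assembly 6 were lower (10 adjusted over the list alone), median -0.13, with Ciao1, of the cytosolic assembly complex, at -0.76 ± 0.12. Bola1 and Glrx5, of mitochondrial cluster transfer, were at -1.05 ± 0.21 and -0.92 ± 0.18, and lost their calls without 10-week KO replicate 1 (adjusted p = 0.0567 and 0.0668) or 2 (0.0689 and 0.0541), and with only the 10-week groups (0.0671 and 0.0657). Of 28 iron-sulfur proteins 8 were lower and 1 higher (8 and 2 adjusted over the list alone), median -0.18, with Ndufs8 at -1.12 ± 0.14 and Ndufs7 at -1.05 ± 0.14. Ndufs8, Ndufs7 and Sdhb (-0.75) are respiratory chain subunits counted in the chain lists above as well, while Xdh (-0.81) is in none of them. The fall of this list is therefore not separate from that of the chain. Of 27 genes of iron uptake, storage and export 5 were higher and 2 lower. Lcn2, which binds iron-carrying siderophores, rose by 2.58 ± 0.15, heme oxygenase, Hmox1, by 2.55 ± 0.25 and the transferrin receptor Tfrc by 1.29 ± 0.17, and Hjv, a co-receptor of hepcidin control, fell by 1.60 ± 0.13. Camera gave an adjusted p of 1.26e-05 for heme, 0.0022 for assembly, 0.00391 for the proteins and 0.567 for iron, and with an estimated correlation 0.11, 0.217, 0.217 and 0.869. Without 10-week KO replicate 1 the lower members were 2 for assembly and 5 for the proteins. The median of assembly was -0.29 and -0.25 without WT replicate 1 and 2 and -0.20 and -0.29 without KO replicate 1 and 2, and that of the proteins -0.33 without WT replicate 1 and -0.29 without KO replicate 2. Without WT replicate 2 camera no longer called the proteins (adjusted p = 0.116).

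Matrix and hypertrophy genes rose at 10 weeks. Of 23 genes of extracellular matrix and fibrosis 20 were higher (22 adjusted over the list alone), median 1.98, with the collagen cross-linking enzyme Lox at 2.89 ± 0.22. Of 16 hypertrophy and fetal cardiac genes 10 were higher and 1 lower (11 and 1 adjusted over the list alone), median 1.15. Myh7, the slow myosin heavy chain, rose by 3.06 ± 0.12, Acta1, skeletal actin, by 2.45 ± 0.22, Fhl1, a sarcomere LIM protein, by 2.27 ± 0.25 and Nppb by 1.65 ± 0.19. Of 24 genes of contraction and calcium handling 6 were lower and 2 higher (8 and 2 adjusted over the list alone), median -0.20, with the potassium channel subunit Kcnip2 at -1.65 ± 0.18, Hrc, a calcium-store protein, at -1.55 ± 0.25 and creatine kinase, Ckm, at -0.99 ± 0.15. Camera gave an adjusted p of 1.05e-25, 2.3e-06 and 0.00848 for these 3 lists, and adjusted p = 0.11, 0.217 and 0.633 with an estimated correlation. Without 10-week KO replicate 2 the hypertrophy list had 6 higher, and without KO replicate 1 the contraction list had 3 lower. The contraction list had 4 higher without WT replicate 2 and 0 higher without KO replicate 2, and its median was -0.34 without WT replicate 1. Camera no longer called the contraction list without WT replicate 2 (adjusted p = 0.571) or KO replicate 1 (0.0745).

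Markers of other cell types moved unequally. Of 22 macrophage and myeloid markers 6 were higher, the same adjusted over the list alone, median 0.47, with Cd68, of the lysosome, at 1.80 ± 0.18, the receptor Csf1r at 1.11 ± 0.18 and the mannose receptor Mrc1 at 1.06 ± 0.15. Of 10 fibroblast markers 6 were higher and 1 lower, the same adjusted over the list alone, median 0.64, with the microfibril genes Mfap4 at 1.84 ± 0.21 and Mfap5 at 1.55 ± 0.21. Of 12 endothelial markers 2 were higher and 1 lower, of 10 smooth muscle and pericyte markers 1 and 2, of 13 lymphocyte markers 0 and 2 and of 8 mesothelial markers 1 and 0. Of 9 atrial markers 1 was higher and 1 lower: Nppa at 1.04 ± 0.24 and Sln at -2.35 ± 0.48. Nppa lost its call without 10-week WT replicate 1 (adjusted p = 0.0851), KO replicate 1 (0.0993) or KO replicate 2 (0.112), and Sln without KO replicate 1 (0.0631) or 2 (0.0789). Of 6 blood markers 1 was lower, the erythrocyte anion exchanger Slc4a1 at -1.15 ± 0.15, and of 11 skeletal muscle markers 1 was higher and 1 lower, Mybpc2, of fast muscle, being at -1.73 ± 0.15. The 7 adipocyte markers had a median of -0.07 and no member past the test. Camera called macrophage (adjusted p = 3.56e-08), fibroblast (0.00123) and blood markers (0.0134), with adjusted p = 0.297, 0.324 and 0.416 with an estimated correlation. Its adjusted p was 0.567 for endothelial, 0.659 for smooth muscle, 0.157 for lymphocyte, 0.67 for mesothelial, 0.567 for atrial, 0.124 for skeletal muscle and 0.866 for adipocyte markers. Without 10-week KO replicate 2 the macrophage list had 11 higher, and without KO replicate 1 it had 4 higher and 1 lower with a median of 0.23. Without KO replicate 1 the fibroblast list had 3 higher and the endothelial list no member past the test, without WT replicate 1 the endothelial list had 0 higher and 2 lower, and without WT replicate 2 the blood list had 4 lower with a median of -0.62. The lymphocyte list had 3 lower without WT replicate 1, 1 without KO replicate 1 and 0 without KO replicate 2, the smooth muscle list 3 lower without WT replicate 1 and 0 higher and 1 lower without KO replicate 1, and the mesothelial list 2 higher without WT replicate 2. The macrophage median was 0.74 without KO replicate 2. The adipocyte median changed sign with single arrays, being -0.51 (1 member lower) and 0.36 without WT replicate 1 and 2 and -0.28 and 0.23 without KO replicate 1 and 2. Atrial markers were 0 higher and 2 lower without WT replicate 1, 3 and 1 without WT replicate 2, and 0 and 0 without either KO array, and skeletal muscle markers 0 and 3 without WT replicate 2. Camera no longer called blood markers without WT replicate 1 (0.155) or KO replicate 2 (0.0775).

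Oxidative stress, interferon and turnover genes changed in part. Of 17 NRF2 targets 5 were higher and 3 lower (6 and 3 adjusted over the list alone), with Srxn1, which repairs peroxiredoxins, at 1.21 ± 0.18 and the glutathione transferase Gsta3 at -1.76 ± 0.30. Of 13 antioxidant enzymes 3 were lower (6, and 1 higher, adjusted over the list alone), median -0.21. Of 15 interferon response genes 5 were lower, the same adjusted over the list alone, median -0.34, with the antiviral enzyme Rsad2 at -1.21 ± 0.16. Of 19 autophagy and lysosome genes 6 were higher and 3 lower, with the protease Ctsl at 1.17 ± 0.12 and the cargo receptor Sqstm1 at 1.10 ± 0.13. Of 14 p53 targets 2 were higher and 3 lower, with the kinase Plk2 at 1.66 ± 0.15 and cyclin G, Ccng1, at -1.09 ± 0.13. Camera called the NRF2 (adjusted p = 0.0159), antioxidant (0.0167) and interferon (0.000887) lists, with adjusted p = 0.217, 0.25 and 0.258 with an estimated correlation. It gave 0.149 for autophagy, which fry called at adjusted p = 0.00933, and 0.567 for p53 targets. Without either 10-week KO array the NRF2 list had 2 higher, the antioxidant list 1 lower and the interferon list 2 lower. The interferon median was -0.15 without WT replicate 1 and -0.56 without KO replicate 2, and the antioxidant median -0.42 without KO replicate 2. Without WT replicate 1 and 2 the antioxidant list had 1 and 5 lower, without WT replicate 1 or KO replicate 1 the p53 list had 1 lower, and without KO replicate 2 the autophagy list had 3 higher and camera no longer called the NRF2 list (adjusted p = 0.0692).

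The remaining lists were not called by camera. Of 17 mitochondrial chaperones and proteases 2 were higher and 3 lower, with the import factor Grpel2 at 1.49 ± 0.15 and the protease Lonp1 at 1.15 ± 0.19 (adjusted p for the list, 0.852). Of 17 glycolysis genes 2 were higher and 4 lower (0.885), with the phosphofructokinase Pfkp at 1.48 ± 0.17 and the muscle enolase Eno3 at -1.05 ± 0.12. Of 15 immediate early genes 4 were higher and 5 lower (0.663), with the nuclear receptor Nr4a1 at 1.59 ± 0.17 and Klf2, a factor of flow-sensing vessels, at -1.24 ± 0.19. Of 19 endoplasmic reticulum chaperones 2 were lower (0.946), of 15 circadian clock genes 2 were higher and 2 lower (0.772), and of 7 metallothioneins and zinc transporters 2 were lower (0.567). Of 21 cell cycle genes 1 was higher and 1 lower (0.752), as of 16 cholesterol synthesis genes (0.772). The counts of these lists moved with single arrays. Without 10-week KO replicate 1 the lower members were 0 for the mitochondrial chaperones, 2 for glycolysis, 3 for immediate early genes and 1 for the endoplasmic reticulum chaperones, and without KO replicate 2 they were 2 for immediate early genes and 0 for the latter. Without KO replicate 2 glycolysis had 1 higher. Without WT replicate 2 the mitochondrial chaperones had 5 higher and 4 lower and the endoplasmic reticulum chaperones 2 higher and 1 lower. The clock list had no member past the test without KO replicate 1, nor the metallothionein and cell cycle lists without either KO array, and the cholesterol list had 0 higher without KO replicate 2 and 0 lower without KO replicate 1. Median and mean had opposite signs for the cell cycle (-0.02 and 0.04) and the endoplasmic reticulum chaperones (0.06 and -0.01), which camera gave as up. They also did for the mitochondrial chaperones (-0.08 and 0.08), which camera gave as down, as it did for glycolysis with a median of 0.01 and a mean of 0.04. These medians lay near 0 and changed sign with single arrays, to -0.05 for the endoplasmic reticulum chaperones and -0.11 for glycolysis without WT replicate 1, 0.20 for the mitochondrial chaperones without WT replicate 2 or KO replicate 1, and 0.10 for the cell cycle without KO replicate 2. With an estimated correlation none of the 42 lists was called at 10 weeks by camera, which called 24 with its preset correlation, 8 up and 16 down, and fry called 23.

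**Figure D3:**
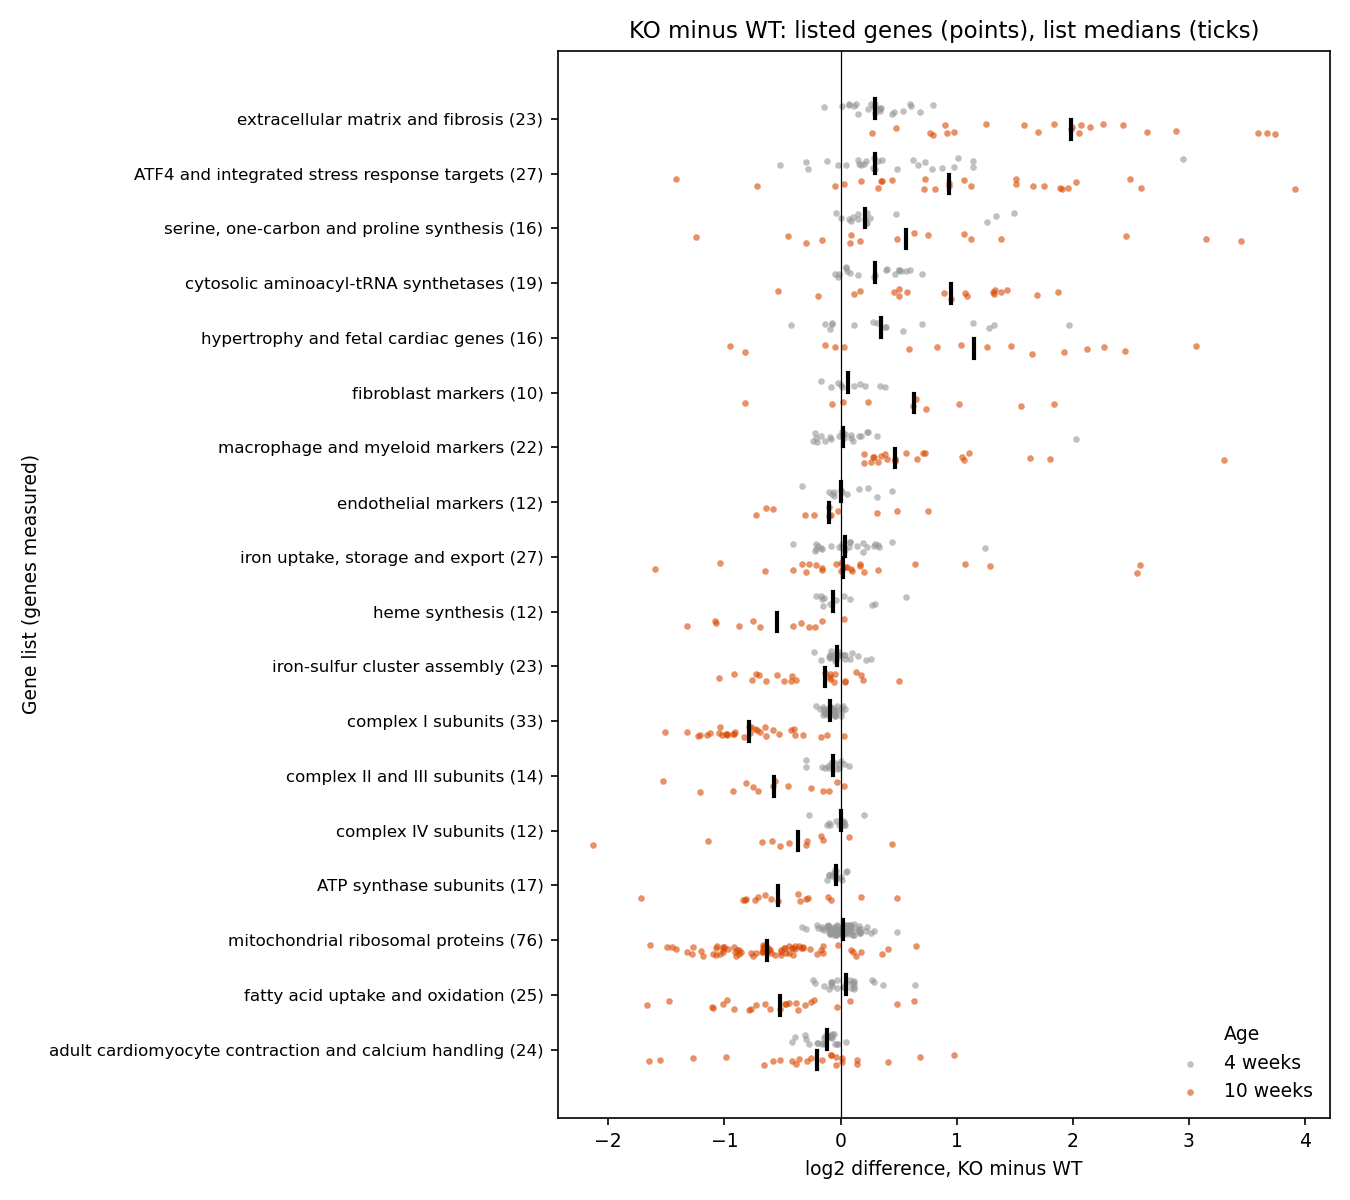
Log2 KO minus WT difference (horizontal axis) of the measured members of gene lists at 4 weeks (grey) and 10 weeks (orange), 1 list per line, with a point per gene and a tick at each list median. The extracellular matrix list has a median of 0.30 at 4 weeks and 1.98 at 10 weeks, and the complex I list -0.09 and -0.79.

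Whether the effect of the deletion differed between the ages was tested as a difference of the 2 differences. Serpina3n differed between the ages by 3.93 ± 0.43 (SE), Postn by 3.07 ± 0.29 and Nox4, an oxidase that makes hydrogen peroxide, by 3 ± 0.22. Rpl3l differed by -3.07 ± 0.21 and Lrtm1 by -2.83 ± 0.28. These 5 had an adjusted p between 0.000814 and 0.00335 and kept their calls without any single array. 379 genes passed, for 160 of which KO minus WT was more positive and for 219 more negative at 10 weeks (limma, Benjamini-Hochberg). Of the 379, 375 had the larger absolute difference at 10 weeks, 130 had opposite signs at the ages, and 375 also differed at 10 weeks by the test of that age. Col8a1 (3.05 ± 0.37) lost its call without 4-week WT replicate 2 (adjusted p = 0.0618) or KO replicate 2 (0.0531), and Gpr22 (-2.81 ± 0.34) without WT replicate 2 (0.0618). The count was 50 and 40 without 4-week WT replicate 1 and 2, and 116 and 53 without 4-week KO replicate 1 and 2. It was 106 and 206 without 10-week KO replicate 1 and 2, and 1600 without 10-week WT replicate 2. Which direction held more genes was not stable: 159 were more positive and 98 more negative with liver and atrial scores as covariates, 65 and 41 without 10-week KO replicate 1, 32 and 18 without 4-week WT replicate 1, and 30 and 23 without 4-week KO replicate 2.

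Over the lists the difference between the ages was tested gene by gene as well, and outside the matrix list few members passed. For the matrix list the difference between the ages passed in 12 of 23 genes (18 adjusted over the list alone), with a median of 1.69. For complex I it passed in 7 of 33, all lower (25 adjusted over the list alone), with a median of -0.70, and for the mitochondrial ribosomal proteins in 10 of 76 (42 adjusted over the list alone), with a median of -0.68. It passed in 2 of 14 subunits of complexes II and III (median -0.47), 2 of 12 of complex IV (-0.38) and 1 of 17 of ATP synthase (-0.48), all lower. For the ATF4 list it passed in 3 of 27 (14 higher and 1 lower adjusted over the list alone), with a median of 0.62. Camera gave an adjusted p of 1.12e-24, 1.93e-19, 3.72e-22 and 9.78e-09 for the matrix, complex I, ribosomal and ATF4 lists, and adjusted p = 0.126, 0.126, 0.254 and 0.254 with an estimated correlation. It called 22 of the 42 lists, and none with an estimated correlation. Fry called 7, among them matrix, complex I and heme synthesis (adjusted p = 0.0101 for each).

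The KO minus WT differences of the ages went the same way in part. Nmrk2, Asns, Nppb and Bdh1 rose at both ages, and Cpxm2, at 0.76 ± 0.24 at 10 weeks, passed at 4 weeks alone on the probe set used (adjusted p = 0.079 at 10 weeks), with a difference between the ages of -1.66 ± 0.34 (0.0467). The other Cpxm2 probe set passed at 10 weeks alone, with 0.30 at 4 weeks (adjusted p = 1) and 0.57 at 10 weeks (0.0287). The expected number of genes called higher at both ages was 0.26. Of 271 genes with an unadjusted p under 0.05 at 4 weeks and called at 10 weeks, 261 went the same way, 96.3%. Across 18193 genes, which are not independent replicates, the differences had a Pearson r of 0.347 and a Spearman rho of 0.226. No array was shared between the ages. The r was 0.207 without 4-week KO replicate 1, and -0.048 with liver and atrial scores as covariates.

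**Figure D4:**
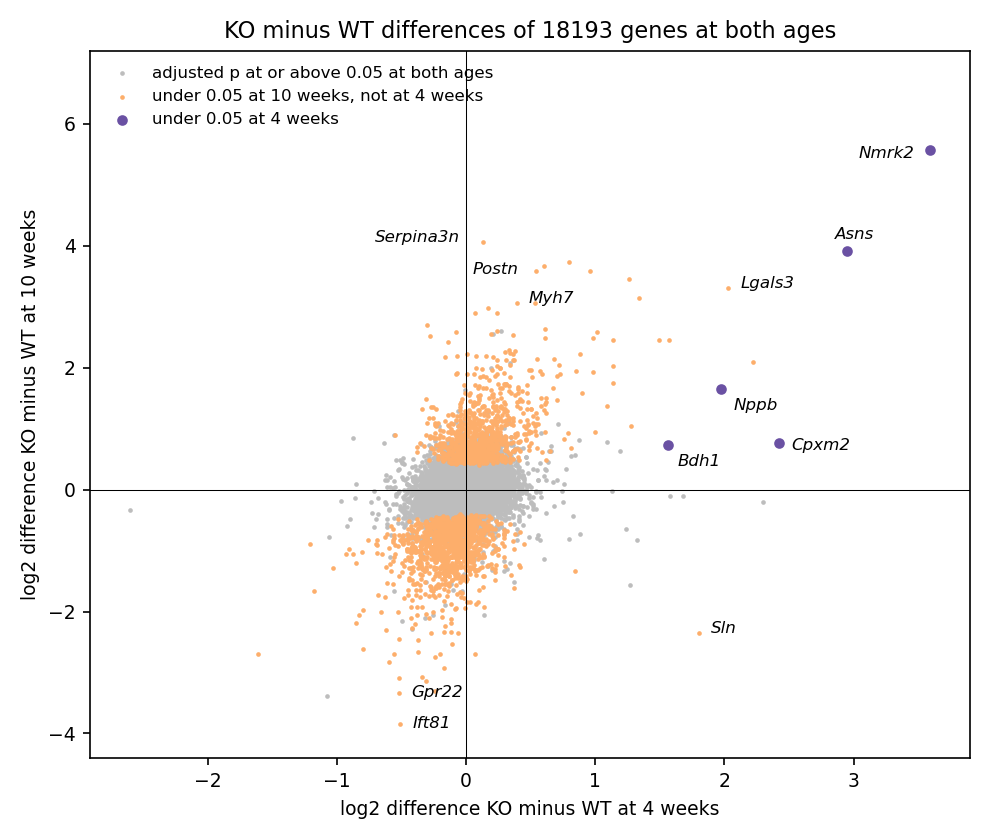
Log2 KO minus WT difference at 4 weeks (horizontal axis) against that at 10 weeks (vertical axis), 1 point per gene, coloured by the age at which its adjusted p was under 0.05. Across genes the Pearson r is 0.347, and Nmrk2 lies at 3.59 and 5.57.

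The ages were also compared within each genotype, where age and litter cannot be told apart. In WT, Bdh1 was higher at 10 weeks by 2.74 ± 0.16 (SE, adjusted p = 0.00032), Cpxm2 by 2.66 ± 0.24 (0.0055) and Nppb by 1.83 ± 0.19 (0.00678), 3 of the 5 genes that rose in 4-week KO. Tfrc fell by 2.13 ± 0.17 (0.00347), and the collagens Col1a1 and Col3a1 differed by -2.11 ± 0.21 (0.00678) and -2.08 ± 0.17 (0.00347). 9 genes were higher and 12 lower in WT (limma, Benjamini-Hochberg), 21 in all. The balance of directions moved with the setting. It was 26 higher and 81 lower with the replicate block, 288 and 990 with liver and atrial scores as covariates, and 2 and 1 with only the WT groups. Nppb lost its call without 4-week WT replicate 1 (adjusted p = 0.054), and Tfrc and Col1a1 without WT replicate 2 (0.0591 for both). With only the 2 WT groups in the model the same differences no longer passed for Cpxm2, Col1a1 and Col3a1 (adjusted p = 0.144 for each), Nppb (0.157) and Tfrc (0.103). The count was 7 and 4 without 4-week WT replicate 1 and 2, 2946 without 10-week WT replicate 2, and 12 without either 10-week KO array. Camera called 12 lists in WT, with matrix genes at a median of -0.44 and 3 of 23 lower (10, and 1 higher, adjusted over the list alone), at adjusted p = 3.07e-05, and adjusted p = 0.844 with an estimated correlation.

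In KO, Serpina3n was higher at 10 weeks by 4.69 ± 0.30, Timp1 by 3.30 ± 0.33, Lgals3 by 3.23 ± 0.26, Myh7 by 3.22 ± 0.12 and Lcn2 by 3.03 ± 0.15. Gpr22 fell by 3.28 ± 0.24, Lrtm1 by 3.27 ± 0.20 and Rpl3l by 3.08 ± 0.15. Their adjusted p lay between 8.12e-06, for Myh7, and 0.000603, for Timp1. Aplnr, the apelin receptor, fell by 3.48 ± 0.56 (0.00504) and lost its call without 4-week KO replicate 2 (0.0685) or 10-week KO replicate 1 (0.0528). Of 1908 genes past the test (limma, Benjamini-Hochberg) 622 were higher and 1286 lower, so 32.6% were higher, and 45.5% after quantile normalization was applied again. 14 genes passed in both genotypes, 12 of them in the same direction. The count in KO was 527 without 4-week KO replicate 2, 1118 without 4-week KO replicate 1, 773 and 1223 without 10-week KO replicate 1 and 2, 1177 without either 4-week WT array and 3035 without either 10-week WT array.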

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

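The tests of cell share, RNA degradation, atrial and liver transcripts below were chosen only after the results were seen, and the test without 10-week WT replicate 1 was chosen before its result. 379 genes had a KO minus WT difference that was not the same at 10 as at 4 weeks, by the test of the difference itself (limma, adjusted p under the threshold of 0.05). Among the named genes the KO minus WT difference at 10 weeks exceeded that at 4 weeks by 3.93 on the log2 scale for Serpina3n, 3.07 for Postn, 3.05 for Col8a1, 3 for Nox4, 2.94 for Timp1, 2.62 for Cilp and 2.19 for Psat1. The difference between the ages was -1.66 for Cpxm2, -3.34 for Ift81, -2.81 for Gpr22, -3.07 for Rpl3l, -2.83 for Lrtm1 and -2.57 for Cmss1. It was -2.73 for Ces1d, -2.76 for Gstk1, -2.23 for Pkd2l2, -2.14 for Asb5 and -4.15 for Sln. For Cpxm2 the 10-week WT level (7.25) was near that of 4-week KO (7), and its test of the difference had an adjusted p of 0.0467. Timp1 lost its call without 4-week WT replicate 1 (adjusted p = 0.128), WT replicate 2 (0.131), KO replicate 1 (0.0792) or KO replicate 2 (0.0837). Sln lost it without 4-week WT replicate 1 (0.129) or 2 (0.0795), or 10-week KO replicate 1 (0.0719) or 2 (0.0704), and Ift81 without 4-week WT replicate 1 (0.07), KO replicate 1 (0.063), KO replicate 2 (0.0659) or 10-week KO replicate 1 (0.0562).

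Probe sets that name no gene or several genes entered no comparison of genes. Of 10092 such probe sets, 292 passed at 10 weeks by the same test, 114 higher and 178 lower, and 1 passed at 4 weeks.

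The respiratory chain subunits were lower in 10-week KO hearts, and the distance of 10-week WT replicate 1 from the other arrays is not enough to account for this, since without that array the complex I median was -0.70 and 26 of 33 subunits were still called. A lower share of cardiomyocytes as the whole cause would lower the contraction genes of these cells as much, and they fell less. The complex I median lay below theirs by a difference of -0.59 (95% bootstrap interval -0.88 to -0.34). Without 10-week WT replicate 1 it did so by -0.35 (-0.58 to -0.15), the smallest gap over the 4 arrays of that age. The bootstrap intervals here resample the genes of a list, which are not independent, and carry no variation between mice. The gap therefore argues against such a share only for these 4 hearts. Fibroblast and macrophage markers exceeded endothelial markers by 0.62 (0.33 to 1.04), but by 0.29 (-0.07 to 0.63) without 10-week KO replicate 1, so this earlier test alone would have left the cardiomyocyte share open, and the contraction gap replaced it with both medians already known. RNA degradation cannot be told apart from the genotype, because the 3' minus 5' signal was higher in KO by 0.08 for the actin controls, where the genotypes overlapped, and by 0.07 for the Gapdh controls, where they did not, and this reading was set after the values were seen, an earlier wording having counted an overlap in 1 control gene against degradation. The Gapdh values of the 10-week KO hearts, -0.10 and -0.11, were near those of 4-week KO replicate 2 (-0.10) and 4-week WT replicate 1 (-0.12). Both shifts were small beside the complex I median of -0.79, and how far shifts of this size could lower the subunits was not tested. A lower expression of the subunit genes through the deletion stays open and was not tested.

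The atrial markers had a median KO minus WT difference of 1.27 at 4 weeks and -0.15 at 10 weeks, where it was -0.26 without WT replicate 1 or KO replicate 1. Unequal amounts of atrium in the dissected hearts may account for the Sln and Myl7 values. 8 atrial markers, with Nppa left out, differed by a median of 0.66 between the 2 hearts of a group. Random lists of like level had a 95th percentile of 0.24 and a highest value of 0.34. The hypertrophy list holds Nppa and also Myl4, which was kept. Genes of random lists need not vary together, so the comparison cannot tell unequal atrium from another source shared by these markers. At 10 weeks Myl4 was lower in KO (11.11 and 10.45, WT 11.39 and 11.8), as Sln and Myl7 were. The atrial marker Bmp10 was not (7.65 and 7.5, WT 6.92 and 7.59). For Nppb at 4 weeks atrium and genotype cannot be told apart, because only 1 KO heart had a WT heart within the Myl7 spread of groups (SD 0.69), a rule set after the values were seen, where an earlier rule asking for 1 such pair had counted against atrium. That KO heart exceeded the WT heart by 1.76 in Nppb, with an SE of 0.26 for a gap between single arrays and a Myl7 gap of 0.14. Within the 4-week KO pair Nppb (12.30 and 12.15) did not follow Myl7 (11.54 and 12.97), within the WT pair it did (9.96 and 10.55, Myl7 10.57 and 11.40), and for these genes a genotype effect stays open. At 10 weeks Nppb was higher in KO (13.81 and 13.64, WT 12 and 12.16) while Myl7 was lower (10.71 and 10.49, WT 11.65 and 12.67). With Myl7 as the measure, this argues against more atrium as the source of the 10-week Nppb difference. It does not decide the question at 4 weeks.

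Liver transcripts varied over the 8 hearts, Alb from 5.19 to 11.05, and at 10 weeks both KO hearts lay below both WT hearts for 12 of the 15 liver markers, at 4 weeks for 0. RNA from liver in some samples is a candidate source: pairs of these markers had a mean correlation of 0.91 across the arrays, against a 95th percentile of 0.10 and a highest value of 0.35 for random lists. Any list of genes that vary together could exceed random lists, so the comparison does not single out this source. The array labels give no tissue other than heart. At 10 weeks 0 of the 15 passed the test of KO against WT, the lowest adjusted p being 0.183 for Alb, so no effect of genotype on them was found, and with 2 hearts per group it stays open.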

How the results depend on the processing

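The covariate setting was chosen only after the data were seen, and the others were planned. For KO against WT at 4 weeks (5 genes) the count was 10 with all probe sets tested singly, 14 with array weights and 13 with only the groups of the comparison, and 3 to 12 over the leave-one-out settings. At 10 weeks (2199) it was 3637 with all probe sets and 959 with only the groups, and 1154 to 3244 over leave-one-out. The difference between ages (379) moved by over 1.5 times only when an array was left out, 40 to 1600. For age in WT (21) the count was 44 with all probe sets, 45 with trend and robust settings, 3 with only the groups, 107 with the replicate block and 1278 with the covariates, and 4 to 2946 over leave-one-out. For age in KO (1908) it was 3262 with all probe sets, and 527 to 3035 over leave-one-out. Agreement between the ages (r = 0.347) was lost, at -0.048, with liver and atrial scores as covariates, and ranged from 0.207 to 0.40 over leave-one-out. All probe sets singly means more tests. Only the groups or an array left out means fewer samples, which does not account for the counts that rose in these settings. These settings also change which pairs enter the shared estimate of the spread. The 10-week WT pair was the least alike (r = 0.9845, against 0.9962 for 4-week WT). KO against WT at 4 weeks and age in KO do not use the means of this pair. Leaving out either of its arrays therefore changes only their estimate of the spread, and the rise of their counts in that setting came from the absence of this pair. Whether its absence raised other counts was not tested. For the array weights, trend and robust settings, block and covariates the cause was not tested. The covariates went with genotype. At 4 weeks the KO atrial scores (-0.18 and 0.89) lay above the WT scores (-0.87 and -0.33). At 10 weeks they (0 and -0.27) lay below the WT scores (0.1 and 0.67). The covariates can therefore take out a genotype difference along with a tissue difference. An error in the fitted atrial effect enters the KO minus WT differences of the ages with opposite signs, which can by itself lower their r. With the replicate block the other counts were 5, 2682, 549 and 2544, within 1.5 times, but the labels do not say whether the replicate numbers pair the mice. Across genes, replicate 2 minus 1 correlated between KO and WT at 0.3 at 4 weeks and 0.23 at 10 weeks. Between groups of different age the correlation was 0.04 to 0.18. What the numbers stand for is not known.

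Under the remaining settings (mean of a gene's probe sets, shared-sequence probe sets left out, both filters on dim genes, quantile normalization again, arrays centred) every count of genes was within 1.5 times. Camera's list calls moved with the filter at a mean log2 of 6. It ended 4 list calls at 4 weeks, 2 at 10 weeks, 3 for the difference between ages and 8 for age in WT, where 2 lists were newly called. Among single genes at 4 weeks, Cpxm2 lost its call with the mean of its probe sets (1.36, adjusted p = 0.0745) and with the covariates, which also ended the calls of Nppb and Bdh1. With the covariates the differences were of like size with a larger SE, on 2 residual degrees of freedom: 2.40 ± 0.36 against 2.42 ± 0.24 for Cpxm2 (adjusted p = 0.201), 1.77 ± 0.28 against 1.97 ± 0.19 for Nppb (0.219) and 1.52 ± 0.23 against 1.56 ± 0.16 for Bdh1 (0.201). Asns kept its call in all settings. Among the named results at 10 weeks, 47 lost their calls with only the groups of the comparison, and 103 kept their status. Calls were lost by 15 with the mean of a gene's probe sets, 15 with the covariates and 11 with array weights. Further calls were lost without single arrays, most without a 10-week KO array. Of the named differences between ages, 1 lost its call with trend and robust settings and 1 with the covariates. Some list counts at 10 weeks also fell with the covariates. 3 of 12 complex IV subunits were lower, against 6, and 6 of 16 genes of the serine list higher, against 9. For the NRF2 and antioxidant lists 1 member each was lower, against 3. Complex I kept 25 of 33 lower, against 26. The 2 hearts per group limit the precision, and genes near the arrays' background limit what a fold can show.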

Other observations

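The gene families and the single gene Scgb1a1 below and the test of shared arrays were chosen only after the results were seen. Genes were also grouped by family name, and some members, such as Kcnip2, Psmb8 and several collagens, were in the lists too. Over all 18193 genes 945 rose and 1254 fell at 10 weeks, and on all arrays the potassium channel genes had no larger share of either. 5 of 18 Asb genes, substrate adaptors of ubiquitin ligases, fell in 10-week KO hearts, and 6 did without 10-week WT replicate 1. Asb5 was at -2.70, Asb15 at -2.62, Asb14 at -2.34, Asb11 at -1.51 and Asb12 at -0.93 on the log2 scale. Of 9 immunity-related and guanylate-binding GTPases 4 fell (3 without that array), Gbp6 at -2.70, Iigp1 at -1.53, Irgm2 at -1.49 and Igtp at -1.44. Of 22 annexin and S100 genes 7 rose and 1 fell (8 and 0 without that array), and of 42 collagens 9 rose (7 without it). Of 44 mitochondrial carriers of the Slc25 family 7 fell and 1 rose (8 and 0 without it), Slc25a26 at -1.42. Of 80 potassium channel genes 5 fell and 2 rose (8 and 0 without it), Kcna5 at -2.11. Of 39 proteasome subunits 3 rose and 6 fell (2 and 2 without it), and 2 of 4 MHC class II genes fell (1 without it).

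Scgb1a1, the secretoglobin of airway epithelium, read log2 9.77 on 10-week KO replicate 1 and between 4.06 and 4.47 on the other arrays.

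3 genes called higher in 4-week KO (Bdh1, Cpxm2 and Nppb) were also called higher in 10-week than in 4-week WT hearts, where 0.0025 were expected for unrelated sets. Both comparisons subtract the same 4-week WT arrays, and whether this accounts for the relation across genes was not settled. The covariance of the 2 sets of differences was 0.0212, against a mean of 0.0187 and a highest value of 0.1554 in 1000 simulations with no effect, 378 of which were at or above it, and the rule for reading this was changed after the values were seen, an earlier one having left the question open. The simulated noise of the shared arrays was drawn from the pairs of every group. The arrays in fact shared were the closest pair (r = 0.9962, against 0.9845 for the 10-week WT pair). The simulated values can therefore be too high, and the test cannot decide the question. The test covers all genes and not these 3. KO minus WT at 10 weeks uses no 4-week WT array. There limma called Nppb (1.65, adjusted p = 0.000763) and Bdh1 (0.73, 0.0143) higher, but not Cpxm2 (0.76, 0.079). For Nppb and Bdh1 this argues against the shared arrays as the sole source of a rise in KO. For Cpxm2 an effect of the deletion beside an effect of age stays open. For all 3 genes age cannot be told apart from litter.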
